A study of Mus musculus with 25 samples.

How the data were processed

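T cell receptor alpha chains were measured in 25 libraries of mouse CD4+ T cells, in 5 groups of 5: resident Treg, circulating Treg, resident Tcell and circulating Tcell of the small-intestine-draining mesenteric lymph node (siMLN), and resident Treg of the colon-draining node (coMLN), all 7 days after photoconversion. Groups and library numbers were taken from the sample titles, and no group was inferred from values. Per the labels' protocols, RNA was reverse transcribed with template switching and an adaptor carrying a unique molecular identifier, then amplified by nested PCR. The labels name neither the clonotype caller nor the steps between reads and clonotypes.

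For each library the authors deposited a count per clonotype, a whole number with no normalization. No label says whether a count is a number of molecules or of reads. The fraction of each clonotype was also deposited, and it equals the clonotype's count over the library total. A deposited table of all libraries holds 11184 clonotypes, 60 of them with a count of 0 in every column, and 25 of 25 library files equalled their column in it. All values below were computed from the library counts. V and J names were compared with mouse gene symbols of the GRCm38.p6 annotation: 103 of 104 V names and 42 of 42 J names matched. No CDR3 held a stop or a frame shift, 10 had 7 or fewer residues and 36 did not start with cysteine; all were kept. No gamma, delta or beta segment was listed.

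Depth was low: the median library held 335 counts, the smallest 42 and the largest 2673. A clonotype seen 0 times in a group was given a floor of 3 counts over the group's total, and shares carry 95% Clopper-Pearson intervals. Diversity was the exponential of the Shannon entropy of nucleotide clonotypes (CDR3, V and J), on the log2 scale, as a mean over 100 random draws (seed 1) to 127 counts for the siMLN groups or to 42 counts for the resident Treg of both nodes. Other values per library were the percent of counts in the 10 largest clonotypes, the percent of clonotypes (CDR3 amino acids and V) also found in another library of the group at that depth, mean CDR3 length, mean Kyte-Doolittle hydropathy of the 5 central residues, and the percent of clonotypes with hydrophobic residues at positions 6 and 7, each clonotype counted once for the CDR3 values. Overlap between libraries was the Morisita-Horn index.

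The comparisons were resident against circulating cells within Treg and within Tcell, Treg against Tcell within resident and within circulating cells, and coMLN against siMLN resident Treg. Single values were compared with 2-sided exact permutation tests over all 252 splits of 5 against 5, whose smallest p is 0.00794, adjusted by Benjamini-Hochberg over the 5 comparisons. The difference between the Treg and Tcell effects was tested by permuting resident and circulating labels within each subtype. Same-number overlap was compared with all 120 pairings of the numbers (1-sided, smallest p 0.00833), and overlaps that share libraries with sign-flip tests over the 5 numbers (smallest p 0.063).

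V and J segment counts were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) in 1 fit of all 25 libraries with the library total as offset, for segments with at least 10 counts in at least 5 libraries and at a false discovery rate of 0.05 over the segments of a comparison. Clonotypes (CDR3 amino acids and V) were tested with edgeR in a separate fit of the 10 libraries of each comparison, among those found in at least 4 of them. That fit used 1 common dispersion for all clonotypes, so its p-values are not on the same footing as those of segments. The fit of segments takes a segment's spread as equal in all 5 groups. Where 1 group spreads more, its p-values can be too small. The fits of segments were tested on 20 simulated data sets with segments changed 2-fold or 4-fold. All segments and groups were simulated with 1 dispersion, unlike the data. Of the calls, 2.08% to 9.62% were false for V segments and 2.86% to 6.21% for J segments, over the comparisons and folds simulated. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

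These comparisons, tests, filters and names were fixed before the data were examined. Named segments were those past the threshold, or the 3 with the lowest p where fewer than 3 passed; named clonotypes were the 3 with the highest mean percent per group and those past the threshold. TRAV6D-6, the TRAV3 and TRAV4 subgroups and the clonotypes of the closing section were named after their values were seen. Lists fixed beforehand were the TRAV6, TRAV7 and TRAV14 families, TRAJ2 to TRAJ30 and TRAJ31 to TRAJ61, with the iNKT receptor (TRAV11, TRAJ18, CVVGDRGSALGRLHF) and the receptor of mucosal-associated invariant T cells (TRAV1, TRAJ33, a CDR3 of 12 residues) as markers of other cell types. That CDR3 of 12 residues had to start with CAVRDSNYQ or CAVMDSNYQ. Exact tests of list and iNKT shares, and V counts summed per subgroup, were added after the data had been seen. Beta chain lists did not apply.

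Alternatives fixed beforehand were other depths, diversity indices, clonotype definitions and overlap indices, removal of clonotypes with a count of 1, count weighting, TMM factors, DESeq2 1.42.0, other filters, fits of 10 libraries, a block for library number, and leaving out each library number. Added after the data had been seen were leaving out TRAV11-TRAJ18 receptors, removing from 4 libraries the clonotypes shared with circulating Treg 1, leaving out those 5 libraries, the share of the 10 largest clonotypes at equal depth with and without TRAV11-TRAJ18 receptors, draws of all receptors to the 93 counts that are left without these, and shared clonotypes of same-number libraries at equal depth. No coordinates were used, and no library was left out of the comparisons.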

Results

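T cell receptor alpha chains were sequenced from CD4+ T cells of the mouse mesenteric lymph node, 7 days after the node had been photoconverted. Photoconversion changes the colour of a light-sensitive protein in the cells present under the light, so that cells which stayed in the node can be told from cells which entered later. The data comprised 25 libraries in 5 groups of 5. From the node segment draining the small intestine (siMLN) came resident regulatory T cells (Treg), circulating Treg, and the resident and circulating cells of the other CD4+ subtype, labelled Tcell. From the node segment draining the colon (coMLN) came resident Treg. The labels name the circulating cells effector/memory cells and the resident cells only T cells, so by label these differ in more than residence. How the Tcell subtype was sorted, and whether iNKT cells were kept or removed, is not stated. Library numbers 1 to 5 recur in each group. No label says that libraries of a group came from separate mice, so p-values measure the spread between these libraries.

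The libraries held 16595 counts in 11124 distinct clonotypes (a nucleotide CDR3 with its V and J segment), and 93.4% of the clonotypes occurred in 1 library. Totals ran from 335 to 1114 counts in siMLN resident Treg, from 206 to 727 in circulating Treg, from 127 to 361 in resident Tcell, from 818 to 2673 in circulating Tcell and from 42 to 260 in coMLN resident Treg. The percent of a library's clonotypes seen with a count of 1 lay between 73.9 and 97.6. Depth therefore differed between groups, and diversity was compared after drawing each library down to 127 counts, or to 42 counts for the resident Treg of both node segments. TRAV7-2 was the most used V segment in resident Treg (6.13% ± 1.92 of counts), circulating Treg (7.34% ± 2.14) and circulating Tcell (5.67% ± 0.483), TRAV4D-4 in coMLN resident Treg (5.57% ± 2.35) and TRAV11 in resident Tcell (14.4% ± 9.19; SD, n = 5 each).

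The first comparison set resident against circulating Tcell, asking whether the cells that stayed in the node carried the same receptors as the circulating cells. The invariant receptor of natural killer T cells (iNKT cells, which recognise lipids presented by CD1d), TRAV11 joined to TRAJ18 with the CDR3 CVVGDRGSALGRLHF, made up 12.3% ± 9.03 of resident Tcell counts and 2.495% ± 1.11 of circulating Tcell counts (SD, n = 5 each). That was a 4.95-fold ratio of means and a difference of 2.10 in mean log2 percent (SE 0.56). Every resident library lay above every circulating one (exact two-sided permutation test, p = 0.00794, adjusted over 5 comparisons 0.0132). The receptor's counts themselves ran from 15 to 37 in resident and from 26 to 109 in circulating libraries. Totals did not overlap (127 to 361 against 818 to 2673 counts), and the smallest resident library had the highest share. The rise in share thus cannot be told apart from library size. Resident Tcell 1 held the highest share, 33 of 127 counts or 25.98% (95% Clopper-Pearson interval 18.6 to 34.5%), and resident Tcell 4 the lowest resident share, 17 of 361 counts or 4.71% (2.77 to 7.43%). Among circulating Tcell the share ran from 1.38% (0.962 to 1.91%) in library 3 to 4.08% (3.36 to 4.90%) in library 5. The receptor was written by 6 nucleotide sequences with 359 counts in all, and the most frequent of them held 149 counts and occurred in all 10 Tcell libraries. Intervals and floors cover counting error only.

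**Figure D1:**
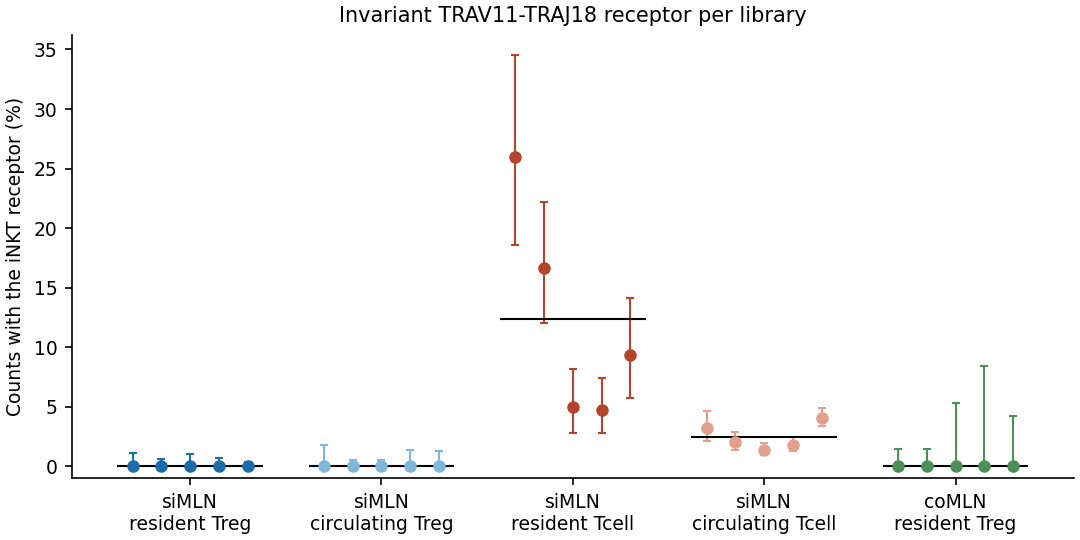
Percent of counts with the invariant TRAV11-TRAJ18 receptor of iNKT cells in each of the 25 libraries, by group (points; bars, 95% Clopper-Pearson intervals; black lines, group means). The 5 resident Tcell libraries lie between 4.71% and 25.98%, the 5 circulating Tcell libraries between 1.38% and 4.08%, and the 15 Treg libraries at 0.

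The resident Tcell repertoire was also less diverse. At 127 counts its effective number of clonotypes (the exponential of the Shannon entropy) was 88.9 ± 16.6 against 114.5 ± 5.24 in circulating Tcell, a log2 difference of -0.38 (exact two-sided permutation test, adjusted p = 0.0397, lower in 5 of 5 libraries than the circulating mean). The 10 largest clonotypes held 22.3% ± 9.12 of resident and 8.61% ± 2.21 of circulating counts (adjusted p = 0.0265, exact permutation test, n = 5 each). A small library has a higher such share by construction. At 127 counts the shares were 25.2% and 14.5% (adjusted p = 0.0397, exact permutation test). Leaving out all TRAV11-TRAJ18 receptors, a choice made after the data had been seen, left 93 counts in the smallest library. At 93 counts the log2 diversity difference was -0.33 with all receptors (adjusted p = 0.0265) and -0.12 without these (adjusted p = 0.0893, exact permutation tests). The share of the 10 largest at that depth was 27.0% against 16.0% with all receptors (adjusted p = 0.0397) and 20.3% against 15.4% without these (adjusted p = 0.109, exact permutation tests).

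**Figure D2:**
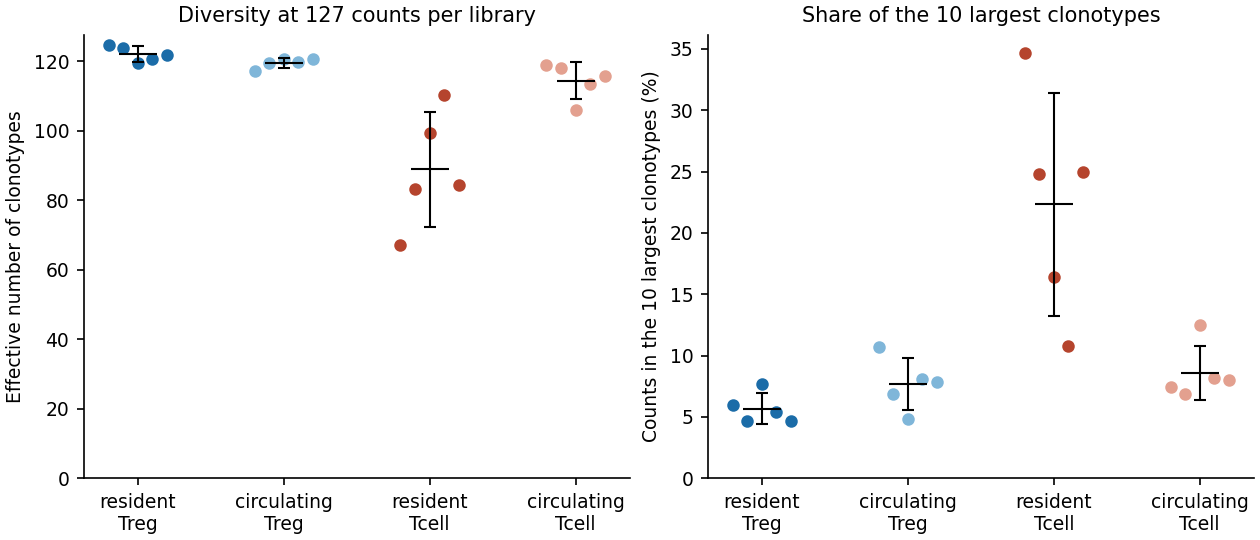
Effective number of clonotypes after drawing 127 counts (left) and percent of counts in the 10 largest clonotypes (right) in each of the 20 siMLN libraries (points; black, mean and SD of 5 libraries). Resident Tcell has a mean effective number of 88.9 against 114.5 to 122.1 in the other groups, and a mean share of 22.3% against 5.67% to 8.61%.

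Of 35 V segments tested with edgeR's quasi-likelihood test, TRAV11 rose in resident over circulating Tcell (log2 fold change 1.92, SE 0.31, adjusted p = 5.25e-07, 14.4% ± 9.19 against 3.55% ± 1.02; SD, n = 5 each). The fit takes the spread as equal in all groups, and TRAV11 spread far more in resident Tcell, so this p can be too small. The exact permutation test of its share had an unadjusted p of 0.00794, the smallest possible. TRAV4D-4 fell (-0.91, SE 0.29, adjusted p = 0.0485, 2.56% ± 1.43 against 5.37% ± 0.786; SD, n = 5 each). Of 34 J segments, TRAJ18 rose (1.20, SE 0.25, adjusted p = 0.000155) and so did TRAJ16 (1.29, SE 0.37, adjusted p = 0.00756), while TRAJ21 fell (-1.38, SE 0.38, adjusted p = 0.00668). At an unadjusted p under 0.05 edgeR had 4 V and 7 J segments, and DESeq2 called 1 V and 2 J segments. All 5 resident libraries lay on that side of the circulating mean for each of these 5 segments. Without TRAV11-TRAJ18 receptors no V segment passed, and TRAJ18 stood at -0.31 (adjusted p = 0.925). The TRAV4D-4 call was lost in 14 of its 15 alternative settings, and those of TRAJ18, TRAJ16 and TRAJ21 ended without library number 2 (0.95, 0.94 and -1.26, adjusted p = 0.0744, 0.161 and 0.0744). The TRAJ21 call also ended with DESeq2 (-1.23, adjusted p = 0.0576). With each clonotype counted once TRAJ21 and TRAJ16 ended (-0.79 and 1.10, adjusted p = 0.292 and 0.0783, edgeR), and with the 10 libraries alone TRAJ16 did (1.30, adjusted p = 0.0615, edgeR).

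None of the V segment lists fixed beforehand held a segment that passed in this comparison: 3 of 5 TRAV14, 1 of 4 TRAV6 and 2 of 6 TRAV7 members had positive log2 fold changes. The same number, 0, passed when adjusted over the list alone. Of 16 segments from TRAJ2 to TRAJ30, 2 rose and 1 fell, and 3 passed when adjusted over the list alone. Of 18 from TRAJ31 to TRAJ61, 0 passed in both ways. Several mouse V segments have near-identical copies, TRAV4D-4 among them, and their assignment is uncertain, so counts were also summed per subgroup, a choice made after the data had been seen. The TRAV6 subgroup then fell (log2 fold change -0.72, SE 0.19, adjusted p = 0.00127, edgeR), from 10.8% ± 1.01 of circulating to 6.09% ± 3.16 of resident Tcell counts, as did the TRAV4 subgroup (-0.64, SE 0.21, adjusted p = 0.0120). The TRAV4 call ended without library number 2 or 3 (-0.59 and -0.57, adjusted p = 0.0774 and 0.0863, edgeR) and with each clonotype counted once (-0.29, adjusted p = 0.443, edgeR). The exact permutation test of the TRAV6 share gave an adjusted p of 0.0529 (n = 5 each).

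Clonotypes found in at least 4 of the 10 Tcell libraries could be tested 1 by 1. None of 29 passed with edgeR or, of 27, with DESeq2, and 3 had an unadjusted p under 0.05 in edgeR. The iNKT receptor was among these, with a log2 fold change of 2.29 (SE 1.10, adjusted p = 0.375, edgeR). It passed with a block for library number (2.11, adjusted p = 0.0320) and among the 9 clonotypes found in at least 5 libraries (2.29, adjusted p = 0.0412, edgeR), where 2 passed. It turned with TMM factors (-0.52, adjusted p = 0.850, edgeR) and with DESeq2 (-0.46, adjusted p = 0.557). Without library number 2 another clonotype passed. The rise stated above is that of the exact test of the receptor's share of counts. The receptor was named before the data were examined, and that test was added afterwards. Apart from it, the most abundant clonotypes of resident Tcell each came from library 5: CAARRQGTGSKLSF (TRAV14-1, TRAJ58) with 10 counts or 4.90% (2.38 to 8.83%), and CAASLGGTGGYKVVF (TRAV14-2, TRAJ12) with 8 counts or 3.92% (1.71 to 7.58%). In circulating Tcell, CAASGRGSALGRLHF (TRAV14D-3/DV8, TRAJ18) held 72 counts or 2.84% (2.23 to 3.56%) of library 3 and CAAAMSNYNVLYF (TRAV7D-2, TRAJ21) 64 counts or 2.52% (1.95 to 3.21%) of the same library.

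CDR3 loops, each clonotype counted once, were longer in resident than in circulating Tcell, 13.63 ± 0.0589 against 13.52 ± 0.0239 residues. Their 5 central residues were less hydrophilic, with a mean Kyte-Doolittle hydropathy of -1.15 ± 0.0655 against -1.28 ± 0.00710 (adjusted p = 0.0198 for both, exact two-sided permutation test, n = 5 each, higher in 5 of 5). Without TRAV11-TRAJ18 receptors the length difference was 0.0690 (adjusted p = 0.139) and the hydropathy difference 0.0951 (adjusted p = 0.0397, both exact permutation tests). Clonotypes with hydrophobic residues at both CDR3 positions 6 and 7 made up 1.24% ± 1.05 and 1.83% ± 0.839 and did not differ (adjusted p = 0.516, exact permutation test, n = 5 each).

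The second comparison put resident against circulating Treg of the siMLN. No difference in diversity, segment usage, clonotypes or CDR3 features passed its test. The effective number of clonotypes lay near its maximum of 127 in both groups, so a rise could hardly show, and a fall shows less than in a group further from it. The effective number at 127 counts was 122.1 ± 2.22 and 119.6 ± 1.37 (log2 difference 0.030, adjusted p = 0.0794), and the 10 largest clonotypes held 5.67% ± 1.24 and 7.66% ± 2.13 of counts (adjusted p = 0.129, exact permutation tests, n = 5 each). Of 35 V segments and 34 J segments 0 passed with edgeR and with DESeq2, and 0 and 1 had an edgeR p under 0.05. The lowest p values among V segments belonged to TRAV11 (-1.17, SE 0.73), TRAV3-3 (0.64, SE 0.42) and TRAV5-1 (-0.83, SE 0.55; adjusted p = 0.822 for each, edgeR). Among J segments they belonged to TRAJ21 (-0.65, SE 0.31), TRAJ49 (0.68, SE 0.35) and TRAJ30 (-0.46, SE 0.31; adjusted p of 0.959 to 0.978). In the fixed lists 4 of 5 TRAV14, 2 of 4 TRAV6, 2 of 6 TRAV7, 7 of 16 TRAJ2 to TRAJ30 and 12 of 18 TRAJ31 to TRAJ61 segments had positive values, with 0 passing, also when adjusted over the list alone. In data simulated at these depths the fit found 33.6% of V segments and 67.9% of J segments changed 2-fold, and 92.9% and 97.1% of those changed 4-fold. The most abundant clonotypes were small: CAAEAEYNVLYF (TRAV4D-3) and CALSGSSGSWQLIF (TRAV12D-2) each had 4 counts or 1.14% (0.310 to 2.88%) in resident Treg 3, and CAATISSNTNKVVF (TRAV7-2) had 12 counts or 1.68% (0.871 to 2.92%) in circulating Treg 2. Of 5 clonotypes that could be tested, 0 passed with edgeR or DESeq2, and 0 had an edgeR p under 0.05.

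CDR3 length (13.44 ± 0.0806 and 13.48 ± 0.155 residues, adjusted p = 0.764) and hydropathy (-1.29 ± 0.0575 and -1.25 ± 0.0743, adjusted p = 0.413) did not separate resident from circulating Treg either (exact permutation tests, n = 5 each). Neither did hydrophobic pairs at positions 6 and 7 (2.03% ± 0.551 and 2.55% ± 1.04, adjusted p = 0.516, exact permutation test). The iNKT receptor had 0 of 2881 counts in resident and 0 of 2200 in circulating Treg, with floors (3 counts over the group) of 0.104% and 0.136%. The difference between residence effects in Treg and Tcell was also tested. Resident minus circulating diversity was higher by 0.41 log2 units in Treg than in Tcell (0.030 and -0.38; p = 0.00321, exact permutation of labels within each subtype), with Treg near the maximum. TRAV11 had an interaction of -3.10 (SE 0.81, adjusted p = 0.00852, edgeR), which was lost without library number 1 (-2.42, adjusted p = 0.403). Of 34 J segments 0 passed with edgeR, with 2 at an unadjusted p under 0.05 (lowest p, TRAJ18 at -1.22, adjusted p = 0.177). DESeq2 was not fitted to the interaction.

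The third comparison asked how Treg differ from Tcell among resident cells. Resident Treg lacked the iNKT receptor. Its mean share over the 5 resident Tcell libraries, with shares from 4.71% to 25.98%, lay 118-fold above a floor of 3 counts over the 5 resident Treg libraries together (exact permutation test, adjusted p = 0.0132, n = 5 each). Resident Treg were more diverse, with an effective number of 122.1 ± 2.22 against 88.9 ± 16.6 (log2 difference 0.48, adjusted p = 0.0397, higher in 5 of 5, exact permutation test). Their 10 largest clonotypes held 5.67% ± 1.24 against 22.3% ± 9.12 of counts (adjusted p = 0.0198, exact permutation tests, n = 5 each). At 127 counts the share was 10.7% against 25.2% (adjusted p = 0.0397, exact permutation test). At 93 counts the diversity difference was 0.40 with all receptors (adjusted p = 0.0265) and 0.18 without TRAV11-TRAJ18 (adjusted p = 0.0397). The share difference was -14.0 and -7.31 percentage points (adjusted p = 0.0397 for both, exact permutation tests). TRAV11 was lower in resident Treg (log2 fold change -5.54, SE 0.48, adjusted p = 2.97e-18), as were TRAJ18 (-2.44, SE 0.29, adjusted p = 2.36e-11) and TRAJ16 (-1.27, SE 0.41, adjusted p = 0.0480, edgeR). Here too the p-values of TRAV11 and TRAJ18 can be too small, since their shares spread far more in resident Tcell than in resident Treg. At an unadjusted p under 0.05 edgeR had 5 V and 5 J segments, and DESeq2 called 1 V and 2 J segments. With the 10 libraries alone, 16 J segments were tested, of which 1 was called higher and 1 lower in resident Treg (edgeR). TRAJ16 no longer passed without library number 1 or 2 (-1.10 and -0.67, adjusted p = 0.181 and 0.542), nor with each clonotype counted once, without a filter or with a block for library number (-1.01, -1.27 and -1.29, adjusted p = 0.157, 0.0666 and 0.0830, edgeR), nor with the clonotypes shared with circulating Treg 1 removed (-1.29, adjusted p = 0.0539, edgeR). Without TRAV11-TRAJ18 receptors TRAV11 (-2.02, adjusted p = 0.301) and TRAJ18 (-0.17, adjusted p = 0.9504, edgeR) did not pass.

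The TRAV6 family, listed before the data were examined and tested as a share afterwards, took 13.2% ± 0.799 of resident Treg and 6.09% ± 3.16 of resident Tcell counts (adjusted p = 0.0397, exact permutation test, n = 5 each, higher in 5 of 5). With 1 library number left out the difference ran from 6.12 to 8.63 percentage points and the call ended in 5 of 5, where the exact test allows no p under 0.0286. Of its 4 tested members all 4 had positive log2 fold changes, led by TRAV6D-6 (1.08, SE 0.46) and TRAV6D-7 (0.98, SE 0.39). Of these, 0 passed over all 35 segments and 2 passed when adjusted over the list alone. Summed per subgroup, TRAV6 had a log2 fold change of 1.00 (SE 0.20, adjusted p = 5.53e-06) and TRAV3 of 1.10 (SE 0.32, adjusted p = 0.00374, edgeR). The TRAV3 call ended without library number 5 (0.96, adjusted p = 0.0527, edgeR). In the TRAV14 family 1 of 5 members, in TRAV7 4 of 6, in TRAJ2 to TRAJ30 12 of 16 and in TRAJ31 to TRAJ61 12 of 18 had positive values. Of these, 2 TRAJ2 to TRAJ30 segments fell, also when adjusted over the list alone, and none of the others passed. Treg CDR3 loops were shorter (13.44 ± 0.0806 against 13.63 ± 0.0589 residues) and more hydrophilic (-1.29 ± 0.0575 against -1.15 ± 0.0655; adjusted p = 0.0198 for both, exact permutation test, n = 5 each). Without TRAV11-TRAJ18 receptors these calls ended (differences -0.143 and -0.0925, adjusted p = 0.0794 and 0.0595, exact permutation tests).

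The fourth comparison set Treg against Tcell among circulating cells. The iNKT receptor had 0 counts in circulating Treg. Its mean share over the circulating Tcell libraries, with shares from 1.38% to 4.08%, lay 18.3-fold above the floor of all circulating Treg libraries together (adjusted p = 0.0132, exact permutation test, n = 5 each). TRAV11 was lower in circulating Treg (-2.45, SE 0.46, adjusted p = 2.59e-05), TRAV7-5 was lower (-1.22, SE 0.36, adjusted p = 0.0177, 1.36% ± 1.07 against 3.63% ± 1.09) and TRAV12D-2 higher (0.82, SE 0.28, adjusted p = 0.0469, 5.29% ± 1.44 against 2.92% ± 0.738). Of the J segments TRAJ18 fell (-1.22, SE 0.29, adjusted p = 0.00212), and TRAJ4 (0.97, SE 0.34, adjusted p = 0.0828) and TRAJ52 (-0.76, SE 0.29, adjusted p = 0.112, edgeR) came next without passing. TRAV7-5 and TRAV12D-2 each lost the call in 4 of the 5 fits that left out a library number. They were lowest in size without number 2 for TRAV7-5 (-1.05, adjusted p = 0.185) and without number 4 for TRAV12D-2 (0.64, adjusted p = 0.550, edgeR). TRAV7-5 also lost it with the 10 libraries alone (-1.22, adjusted p = 0.0548), and TRAV12D-2 with TMM factors and without a filter (0.76 and 0.82, adjusted p = 0.141 and 0.106, edgeR). TRAV12D-2 lost it too with the clonotypes shared with circulating Treg 1 removed (0.82, adjusted p = 0.0617) and without TRAV11-TRAJ18 receptors (0.77, adjusted p = 0.0785, edgeR). Without these receptors TRAV11 (-0.28, adjusted p = 0.851) and TRAJ18 (-0.45, adjusted p = 0.509, edgeR) did not pass either. TRAJ18 lost it without number 2 (-1.07, adjusted p = 0.123), with DESeq2 (-1.16, adjusted p = 0.0728) and with each clonotype counted once (-0.37, adjusted p = 0.430, edgeR). TRAV11 lost it with each clonotype counted once (-1.23, adjusted p = 0.0648, edgeR). At an unadjusted p under 0.05 edgeR had 3 V and 6 J segments, and DESeq2 called 3 V and 0 J segments.

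Of 21 testable clonotypes, 2 passed in circulating cells: the iNKT receptor (adjusted p = 0.000202) and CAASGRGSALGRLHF on TRAV14D-3/DV8 with TRAJ18 (adjusted p = 0.0407, edgeR), with 0.669% ± 1.22 of circulating Tcell counts (n = 5) and 0 of 2200 circulating Treg counts, with a floor of 0.136%. Most of its counts, 72, came from circulating Tcell 3. The call ended without library number 2, 3 or 5 (log2 fold changes -6.36, -3.65 and -6.11, adjusted p = 0.0623, 0.373 and 0.0534, edgeR), against -6.04 with all libraries. Both clonotypes met the filter of 4 libraries through circulating Tcell alone, which held 9599 counts against 2200 in circulating Treg. That filter is thus met more easily by clonotypes of circulating Tcell. The effective number was 119.6 ± 1.37 in circulating Treg and 114.5 ± 5.24 in circulating Tcell (log2 difference 0.064, adjusted p = 0.0529), and the 10 largest clonotypes held 7.66% ± 2.13 and 8.61% ± 2.21 (adjusted p = 0.484, exact permutation tests, n = 5 each). The TRAV6 family took 13.7% ± 2.00 and 10.8% ± 1.01 of counts (adjusted p = 0.0529). In the fixed lists 0 of 5 TRAV14, 3 of 4 TRAV6, 5 of 6 TRAV7, 10 of 16 TRAJ2 to TRAJ30 and 6 of 18 TRAJ31 to TRAJ61 segments had positive values. Of these lists 1 TRAV7 member fell, also when adjusted over the list alone, and 1 TRAJ2 to TRAJ30 segment fell, with 2 passing when adjusted over that list alone. CDR3 length (13.48 ± 0.155 and 13.52 ± 0.0239) and hydropathy (-1.25 ± 0.0743 and -1.28 ± 0.00710) did not differ (adjusted p = 0.833 and 0.413, exact permutation tests, n = 5 each).

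The fifth comparison set resident Treg of the coMLN against those of the siMLN, asking whether the draining site of the node shapes the Treg repertoire. The coMLN libraries were the smallest. Libraries 2, 3 and 5 shared many clonotypes with circulating Treg 1, as given below. Drawn down to 42 counts, the effective number was 39.6 ± 2.48 in coMLN and 41.4 ± 0.248 in siMLN (log2 difference -0.067, adjusted p = 0.0794, lower in 5 of 5), with siMLN near the maximum of 42. The 10 largest clonotypes held 18.2% ± 11.5 of coMLN and 5.67% ± 1.24 of siMLN counts (adjusted p = 0.0198; difference 12.6, and 8.11 without number 4), but at equal depth the difference was 3.33 percentage points (adjusted p = 0.0794, exact permutation tests, n = 5 each). Of 35 V and 34 J segments 0 passed with edgeR and with DESeq2, and 1 and 2 had an edgeR p under 0.05. The lowest p values belonged to TRAV12-3 (1.08, SE 0.48), TRAV17 (1.09, SE 0.58) and TRAV7-3 (-1.12, SE 0.61; adjusted p = 0.593 for each) and to TRAJ57 (1.02, SE 0.47), TRAJ39 (-1.06, SE 0.52) and TRAJ30 (0.74, SE 0.38; adjusted p = 0.598 for each, edgeR). In simulated data at these depths the fit found 16.4% of V segments changed 2-fold and 79.3% of those changed 4-fold, so that 2-fold changes were mostly not detectable.

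In the fixed lists 1 of 5 TRAV14, 1 of 4 TRAV6, 4 of 6 TRAV7, 6 of 16 TRAJ2 to TRAJ30 and 11 of 18 TRAJ31 to TRAJ61 segments were positive in coMLN over siMLN, with 0 passing, also when adjusted over the list alone. Length (13.53 ± 0.162 and 13.44 ± 0.0806 residues, adjusted p = 0.463) and hydropathy (-1.38 ± 0.166 and -1.29 ± 0.0575, adjusted p = 0.413) did not differ between node segments (exact permutation tests, n = 5 each), nor did hydrophobic pairs (2.21% ± 0.923 and 2.03% ± 0.551, adjusted p = 0.706). The iNKT receptor had 0 of 702 coMLN counts, with a floor of 0.427%. No clonotype count fit could be made here, and the most abundant clonotypes had 2 counts each in library 4, such as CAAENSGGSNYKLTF (TRAV4D-3, 4.76%, 0.582 to 16.2%).

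Public receptors, meaning a CDR3 amino acid sequence with its V segment found in another library of the group at equal depth, were compared at 127 counts in the siMLN groups. They made up 4.59% ± 1.54 of resident and 2.67% ± 0.462 of circulating Tcell clonotypes. In Treg they made up 1.27% ± 0.199 in resident and 1.24% ± 0.470 in circulating cells (adjusted p = 0.0397 for resident against circulating Tcell and for Treg against Tcell in either state, exact permutation tests, n = 5 each). A library's value depends on the other libraries of its group. The 5 values are thus not independent, as these tests take them to be, which limits the p-values of this measure. The difference between resident and circulating Tcell was 1.93 and fell to 0.846 without library number 1 and to 0.818 without number 3. Treg minus Tcell was -3.32 in resident cells (-2.20 without number 1, -1.94 without number 3) and -1.43 in circulating cells (-0.914 without number 5). At 93 counts the resident minus circulating Tcell difference was 1.92 with all receptors (adjusted p = 0.0132) and 1.41 without TRAV11-TRAJ18 (adjusted p = 0.129, exact permutation tests). At 42 counts the value was 5.45% ± 4.70 in coMLN resident Treg against 0.558% ± 0.243 in siMLN (adjusted p = 0.129, exact permutation test, n = 5 each), and the coMLN value stood at 0.345% once the clonotypes shared with circulating Treg 1 had been removed.

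Clonotype sharing asked which populations draw on the same cells. The Morisita-Horn index, which is 0 for no overlap and 1 for equal repertoires, was 0.213 ± 0.0189 between resident and circulating Tcell of the same number and 0.119 between those of different numbers (adjusted p = 0.0139, exact one-sided test over all 120 pairings, n = 5). The difference of these 2 was 0.0934, and 0.0622 without number 3. Same-number resident and circulating Tcell libraries had 15 to 60 nucleotide clonotypes in common, which took 35.6% ± 4.41 of resident and 9.11% ± 2.77 of circulating counts (SD, n = 5). Such counts of shared clonotypes grow with the depth of both libraries. Drawn to 127 counts, these libraries shared 5.83 ± 0.915 clonotypes and those of resident and circulating Treg 1.43 ± 0.730 (SD, n = 5 each). The shared clonotypes of Tcell include iNKT sequences, of which every Tcell library held 4 or 5 and no Treg library any. Numbers of shared clonotypes were not computed without these. Without TRAV11-TRAJ18 receptors the index was 0.117 for the same and 0.00846 for different numbers (adjusted p = 0.0139, exact test). Resident and circulating Treg of the same number overlapped less, at 0.0380 ± 0.0211 against 0.00634 for different numbers (adjusted p = 0.0139, exact test, n = 5), with 3 to 25 clonotypes in common that took 3.56% ± 2.57 of resident counts. The difference between the Treg and the Tcell overlap was -0.175 (p = 0.00794, exact permutation test of 5 against 5), and -0.0794 without TRAV11-TRAJ18 receptors (p = 0.0397, exact permutation test).

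Overlap was also measured across subtypes and node segments. Resident Treg and resident Tcell of the same number had an index of 0.00435 ± 0.00467 against 0.000720 for different numbers (difference 0.00363, and 0.00239 without number 4). Circulating Treg and circulating Tcell had 0.0115 ± 0.00727 against 0.00470 (adjusted p = 0.0167 for both, exact tests). Resident Treg of siMLN and coMLN had 0.0182 ± 0.0128 against 0.00282 (adjusted p = 0.0139, exact tests over all 120 pairings, n = 5 each). Resident Treg shared more with circulating Treg than with resident Tcell in 5 of 5 numbers (difference 0.0337, p = 0.063, exact sign-flip test, the smallest that 5 numbers allow), and more than with coMLN Treg in 4 of 5 (0.0198, p = 0.188, exact sign-flip test). Drawn to 42 counts, resident Treg shared 0.176 clonotypes with circulating Treg and 0.206 with coMLN Treg (means of 5 numbers).

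Over the 241 pairs of different numbers that held at most 1 of the 5 libraries named next, the median was 0.857% of the smaller library's nucleotide clonotypes shared. Of the 188 clonotypes of circulating Treg 1, 52 occurred in coMLN Treg 5, 50 in coMLN Treg 2, 17 in coMLN Treg 3 and 10 in resident Tcell 2. These made up 62.4%, 20%, 29.4% and 4.505% of the counts of those libraries. As a percent of the smaller library, circulating Treg 1 shared 62.7%, 26.6% and 27.4% with coMLN Treg 5, 2 and 3, above the highest value of 10.8% among the 241 pairs of different numbers with at most 1 of these 5 libraries, and 6.10% with resident Tcell 2, below it. Leaving out the 5 libraries kept the iNKT and diversity results for Tcell (iNKT difference 8.76 percentage points, adjusted p = 0.0198; log2 diversity difference -0.37, adjusted p = 0.0397, exact permutation tests). It ended the calls of TRAV4D-4, TRAJ16, TRAJ21, TRAV7-5, TRAV12D-2, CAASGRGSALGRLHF in circulating cells, the TRAV4 subgroup, the TRAV11 interaction, the coMLN share of the 10 largest and public receptors in resident against circulating Tcell. Fewer libraries remain then, and several of these calls also ended with 1 library number left out. With only the shared clonotypes removed, 3 J segments and 3 V subgroups were still called for resident against circulating Tcell, and 1 V segment in the interaction. No V segment was then called lower in resident than in circulating Tcell, or higher in circulating Treg than in circulating Tcell.

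**Figure D3:**
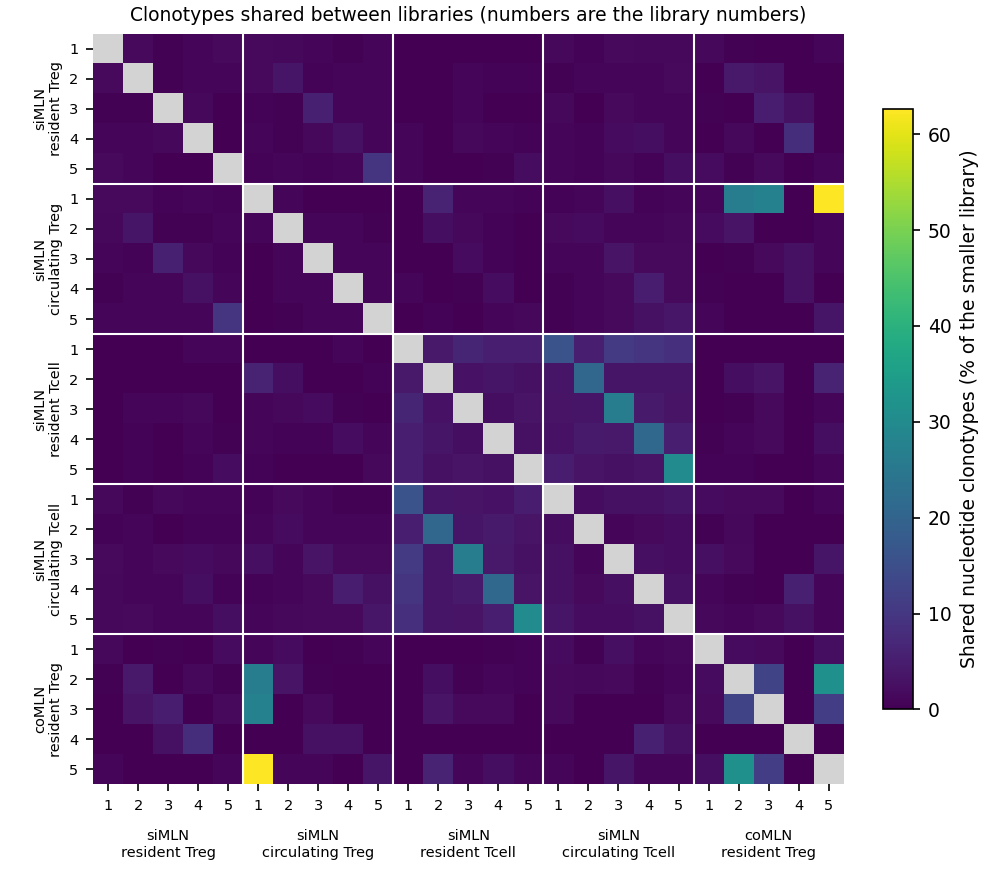
Nucleotide clonotypes shared by each pair of the 25 libraries, as a percent of the smaller library's clonotypes (colour), with libraries ordered by group and number on both axes and each library against itself in grey. Same-number pairs of resident and circulating Tcell reach 30.1%, and circulating Treg 1 stands out with coMLN resident Treg 2, 3 and 5, up to 62.7%.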

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

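Apart from the test of each clonotype counted once and the test of small libraries with coMLN Treg, the tests of explanations in this part were chosen after the result they address had been seen.

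Circulating Treg 1 shared 86 of its 188 nucleotide clonotypes with coMLN Treg 2, 3 and 5 and resident Tcell 2, and 62.7% of the clonotypes of coMLN Treg 5 were among them. Public receptors made anew in each animal are argued against: among 10 Treg libraries with more clonotypes than circulating Treg 1, the highest held 3.61% of the coMLN Treg 5 clonotypes. That test replaced an earlier one after its value had been seen: 20 of the 86 shared receptors, by CDR3 amino acids and V, occurred in any of the 20 other libraries, against 12.7% of the other clonotypes of circulating Treg 1, so public receptors may make up a part. Clones of 1 animal sampled in both libraries are argued against too, since 63.0% of the coMLN Treg 5 clonotypes with a count of 1 recurred in circulating Treg 1, where the highest value for any same-number pair was 26.9%. Carry-over of material or reads from 1 source may account for the sharing: of the clonotypes shared by any pair of the 4 libraries, 97.3% were in circulating Treg 1, at a step the labels do not give.

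The iNKT receptor took a larger share of counts in resident than in circulating Tcell. Library size cannot be told apart from residence here, since no circulating library had as few counts as a resident one. Carry-over that reached all libraries alike is argued against, since the receptor was absent from the 15 Treg libraries, with an upper limit of 0.0519% over all of them together. Carry-over among the Tcell libraries alone was not tested, since Treg libraries cannot show it. 1 amplified nucleotide variant in each library is argued against as the whole cause: without each library's most frequent variant 7.43% of resident and 1.40% of circulating counts remained (difference 6.03 percentage points, p = 0.00794, exact permutation test; 4.06 without library number 1). Amplification of several molecules cannot be told apart from more cells: with each nucleotide clonotype counted once the difference was 2.33 percentage points (2.74% against 0.409%), but every Tcell library held 4 or 5 variants, so the number of other clonotypes set that value and the bound chosen beforehand was wrong. A larger share of iNKT cells among the cells that stay in the node is a candidate explanation from the design, as is the effector/memory state that the labels give for circulating cells alone; neither was tested, and CD1d tetramer staining of both populations would test the first.

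Resident Tcell were less diverse than resident Treg and than circulating Tcell, which had no library of like size (at least 818 counts, against at most 361) and alone of these 2 Tcell groups bear the effector/memory label, so that state and residence stay open, untested. Against circulating Tcell, iNKT receptors alone may account for it: at 93 counts the log2 difference was -0.33 with all receptors and -0.12 without TRAV11-TRAJ18 (p = 0.0159 and 0.0714, exact permutation tests). Against resident Treg they are argued against as the whole cause, since of 0.40 at that depth 0.18 remained (p = 0.00794, exact permutation test). Small libraries are argued against as the whole cause for resident Tcell 2 to 5, by resident and circulating siMLN Treg of like size. These were resident Treg 1 and 3 (335 and 352 counts) and circulating Treg 1, 4 and 5 (206, 271 and 282). At 127 counts these 5 had an effective number of 120.4 ± 2.74. Resident Tcell 2 to 5, of 204 to 361 counts, had 94.4 ± 12.9 (log2 difference 0.36, p = 0.00794, exact permutation test). Without the sharing libraries (here circulating Treg 1 and resident Tcell 2) the difference was 0.31 (p = 0.0286, exact permutation test). No resident Treg library held fewer than 335 counts, so resident Treg alone cannot decide this for resident Tcell 2, 3 and 5. Over all 5 resident Tcell libraries, small libraries cannot be told apart from the subtype: at 42 counts the still smaller coMLN Treg had 39.6 ± 2.48 and resident Tcell 35.7 ± 3.85 (log2 difference 0.16, p = 0.0794, exact permutation test, n = 5 each), and within resident Tcell the effective number was 67.02 in the library of 127 counts and 110.3 in that of 361.

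Among 114 groups of 5 values, 5 had a value far from the others, and chance gives about 1 in 20 groups. Circulating Tcell 3 had 12.5% of counts in its 10 largest clonotypes, against a group mean of 8.61%. Circulating Treg 2 had a mean CDR3 length of 13.2 residues, against 13.48 for its group. TRAV12D-2 took 7.75% of counts in circulating Treg 4 (group mean 5.29%) and 4.21% in circulating Tcell 2 (2.92%), and TRAJ21 3.69% in resident Treg 3 (2.53%).

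The resident minus circulating difference was tested between Treg and Tcell, and these values passed. Log2 diversity differed by 0.41 (p = 0.00321; Treg, at 122.1 and 119.6 of at most 127, had little room to rise), the share of the 10 largest clonotypes by -15.7 percentage points (p = 0.0017), public receptors by -1.90 (p = 0.0421), the iNKT share by -9.84 (p = 0.00794; every Treg library held 0, so this restates the difference within Tcell), hydropathy by -0.170 (p = 0.00702) and the TRAJ2 to TRAJ30 share by -10.8 (p = 0.0483; exact permutation tests, n = 5 each). Resident-circulating overlap differed by -0.175 (p = 0.00794, exact permutation test, n = 5 each). TRAV11 differed by -3.10 as a segment (edgeR, adjusted p = 0.00852) and by -3.02 as a subgroup (edgeR, adjusted p = 0.000832). Without library number 1 both calls ended, at -2.42 and -2.37 (edgeR, adjusted p = 0.403 and 0.124). Hydropathy was then -0.130 (p = 0.0576, exact permutation test). At equal depth the share of the 10 largest clonotypes differed by -12.1 (p = 0.00208, exact permutation test). Values of public receptors within a group depend on one another, which limits their p-values. Public receptors differed by -1.08 without number 1 (p = 0.0188), -0.602 without number 3 (p = 0.161) and -1.87 without number 4 (p = 0.116, exact permutation tests). They differed by -0.389 with amino acid CDR3 alone (p = 0.661), -1.44 without TRAV11-TRAJ18 receptors (p = 0.0702) and -1.885 with the 5 sharing libraries left out (p = 0.0587, exact permutation tests). The TRAJ2 to TRAJ30 share differed by -5.84 without number 1 (p = 0.324), -7.54 without number 2 (p = 0.190) and -12.5 without number 5 (p = 0.0694), by -6.31 without TRAV11-TRAJ18 receptors (p = 0.156) and by -5.70 with the 5 libraries left out (p = 0.185, exact permutation tests).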

How the results depend on the processing

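The alternatives without TRAV11-TRAJ18 receptors, with shared clonotypes removed, with the 5 sharing libraries left out, with the 10 largest clonotypes at equal depth and with all receptors at the depth left without TRAV11-TRAJ18 were chosen after the data had been seen, as were V subgroups and the alternatives for list and iNKT shares. Over 62 results that answer a comparison, 783 alternative values were computed: 579 kept direction and side of the threshold, 107 kept direction and no longer passed, 13 newly passed, 64 counts or values moved and 20 turned. Over the other results 833 of 979 values kept both, 107 no longer passed, 9 newly passed and 30 turned. Unless a reason is given, the cause of a change was not tested. Without a number, 4 against 4 libraries have a smallest exact permutation p of 0.0286, so some calls end there by construction. Depth limits what can be seen: in simulated data 33.6% of 2-fold V changes were found for resident against circulating cells and 16.4% for coMLN. In order, A is resident against circulating Treg, B resident against circulating Tcell, C resident Treg against resident Tcell, D circulating Treg against circulating Tcell and E coMLN against siMLN resident Treg; overlap pairs are named in full. No clonotype fit could be made for E under any setting, nor the replicate block and DESeq2 fits of the 1 clonotype of C.

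At a 50% depth, log2 diversity newly passed for A (0.015), D (0.039) and E (-0.035), and public receptors turned for A (-0.0202). With no drawing to equal depth, diversity was -1.45 for D and -2.17 for E, and public receptors -3.63 for B, -0.928 for C and 4.57 for the interaction; the libraries then differ in depth by construction. With the inverse Simpson index D was 0.11. With amino acid CDR3 alone, diversity for D was 0.080, public receptors were 1.01 for B, -1.19 for C and -0.806 for D, and same-number minus different-number overlap was 0.00474 for resident Treg with resident Tcell, 0.00479 for circulating Treg with circulating Tcell and 0.0128 for siMLN with coMLN. The largest 1 clonotype gave -0.530 for A, the largest 50 gave 3.12 for D, and equal depth 3.33 for E, also without TRAV11-TRAJ18 receptors, which no Treg library held.

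With clonotypes of count 1 removed, log2 diversity was 0.50 for C and -0.33 for D, CDR3 length 0.256 for B and -0.405 for C, hydropathy 0.237 for B, -0.348 for C, -0.0247 for D and 0.181 for E, hydrophobic pairs 0.525 for A and -0.437 for E, and same-number minus different-number overlap 0 for resident Treg with resident Tcell, 0.00445 for circulating Treg with circulating Tcell and -0.00162 for siMLN with coMLN. Weighted by count, hydropathy for D was -0.0151. With each clonotype counted once, the TRAV7 family share was 1.08 for B, -0.879 for C and -2.12 for the interaction, and calls were 1 V and 1 J segment for B and 0 J segments for D.

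Without TRAV11-TRAJ18 receptors, log2 diversity was -0.12 for B and the share of the 10 largest at equal depth 4.91 for B; public receptors -0.0294 for A, 1.41 for B and -0.531 for D; CDR3 length 0.0690 for B and -0.143 for C; hydropathy -0.0925 for C; the TRAV7 family share 0.806 for B, -2.12 for C and -2.24 for the interaction. TRAJ18 was -0.31 for B and 0.28 for the interaction. V segment calls were 0 for B, 0 for C, 1 for D and 0 for the interaction, J segment calls 1 for C and 0 for D, and V subgroup calls 0 for D and 0 for the interaction. The smallest siMLN library then held 93 counts. With all receptors at that depth, diversity was -0.33 for B and newly passed for D (0.051), public receptors were 1.92 for B and turned for A (-0.0294), and the share of the 10 largest was 10.97 for B and 3.33 for E, drawn to 42 counts as before.

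With the clonotypes shared with circulating Treg 1 removed, diversity was 0.064 for D and -0.061 for E, public receptors -0.0953, hydrophobic pairs -0.202, the TRAV14 family 0.206 and the TRAV6 family 0.0497 for E, with 1 V segment call for B and 1 J segment call for C. With the 5 libraries left out, the share of the 10 largest was 16.6 for E, public receptors 2.04 for B and -0.558 for E, and same-number minus different-number overlap 0.0378 for resident with circulating Treg, 0.105 for resident with circulating Tcell, 0.00478 for resident Treg with resident Tcell, 0.00869 for circulating Treg with circulating Tcell and 0.0149 for siMLN with coMLN, where fewer numbers leave fewer pairings. V segment calls were then 1 for B, 1 for D and 0 for the interaction, J segment calls 1 for B and 1 for C, V subgroup calls 1 for E and 0 for the interaction, and clonotype calls 1 for D.

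With TMM factors there was 1 V segment call for B and 7 clonotype calls for D. Without a filter there were 1 V call for B, 3 V calls for C and 1 J call for C. With the 10 libraries alone there was 1 V call for B and 2 J calls for D. Exact permutation tests of shares gave 0 V calls and 0 J calls for each of B, C and D, since their smallest p, 0.00794, passes the adjustment only when many segments reach it. DESeq2 gave 1 V call for B and 0 J calls for D. Clonotypes in at least 5 libraries gave 2 calls for B and 1 for D, and in at least 3 libraries 4 calls for C.

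Same-number libraries did not all correlate above 0.1, so the numbers were not used to pair the libraries, although same-number libraries overlapped more than others. As 93.4% of clonotypes occurred in 1 library, such correlations stay low, and this cut-off does not show that the numbers are unrelated. The main tests of 5 against 5 thus leave aside any link between same-number libraries. Correlations of deviations ran from 0.0104 to 0.0486 for resident with circulating Treg, from 0.0541 to 0.141 for resident with circulating Tcell (4 of 5 above 0.1), from -0.000276 to 0.00811 for resident Treg with resident Tcell, from -0.00229 to 0.0150 for circulating Treg with circulating Tcell and from 0.00736 to 0.0271 for siMLN with coMLN. As a hint from the data, every library correlated best with its own number in the first 2 of these pairs (5 of 5 in both directions). In the 2 directions it was 5 and 4 of 5 for siMLN with coMLN. It was 3 and 4 for circulating Treg with circulating Tcell, and 3 and 3 for resident Treg with resident Tcell. Under the replicate block, exact sign-flip tests over 5 numbers cannot give a p under 0.063, so none of these could pass: diversity -0.38 for B, 0.48 for C and 0.41 for the interaction; share of the 10 largest 13.7 for B, -16.7 for C and 12.6 for E; public receptors 1.93 for B, -3.32 for C and -1.43 for D; iNKT share 9.84 for B, -12.3 for C, -2.495 for D and -9.84 for the interaction; CDR3 length 0.110 for B and -0.195 for C; hydropathy 0.130 for B and -0.137 for C; overlap difference -0.175. In edgeR the replicate block gave 3 V calls and 1 J call for C, 2 V subgroup calls for the interaction and 1 clonotype call for B.

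Leaving out each number in turn gave these ranges. Log2 diversity: 0.015 to 0.042 for A, -0.47 to -0.27 for B and 0.37 to 0.57 for C, and the calls of B and C each ended in 4 of 5. Share of the 10 largest: -3.19 to -1.302 for A, 10.3 to 16.5 for B, -19.5 to -13.6 for C, -1.99 to 0.720 for D and 8.11 to 14.95 for E. The calls of B, C and E each ended in 3 of 5. Public receptors: -0.255 to 0.421 for A, 0.818 to 2.29 for B, -3.88 to -1.94 for C, -1.59 to -0.914 for D, 1.03 to 6.28 for E and -2.38 to -0.602 for the interaction. These calls ended in 3 of 5 for B and in 2 of 5 for C and for D. CDR3 length: -0.102 to 0.0123 for A, 0.0870 to 0.129 for B, -0.215 to -0.176 for C and -0.0762 to 0.0118 for D. Hydropathy: 0.111 to 0.150 for B and -0.167 to -0.0937 for C. For CDR3 length and hydropathy the calls of B and C ended in 5 of 5, where 2 comparisons at the smallest exact p cannot pass the adjustment. Hydrophobic pairs: -0.0606 to 1.06 for D, -0.190 to 0.551 for E and -0.508 to 0.506 for the interaction. TRAJ2 to TRAJ30 share: -3.48 to 4.22 for E and -14.3 to -5.84 for the interaction. TRAV14 family: -1.995 to 2.20 for B and -2.55 to 0.731 for C. TRAV6 family: 6.12 to 8.63 for C, where the call ended in 5 of 5, and -2.17 to 0.744 for E. TRAV7 family: -3.53 to 0.386 for A, -0.442 to 2.33 for C, -0.502 to 2.44 for D, -3.55 to 0.0459 for E and -2.88 to 2.83 for the interaction. Same-number minus different-number overlap: 0.0264 to 0.0378 for resident with circulating Treg, 0.0622 to 0.111 for resident with circulating Tcell, 0.00239 to 0.00478 for resident Treg with resident Tcell, 0.00537 to 0.00869 for circulating Treg with circulating Tcell and 0.0115 to 0.0190 for siMLN with coMLN. V segment calls: 1 to 1 for B, 1 to 2 for C, 1 to 2 for D and 0 to 1 for the interaction. J segment calls: 0 to 4 for B, 1 to 3 for C and 0 to 1 for D. V subgroup calls for the interaction: 0 to 2. Clonotype calls: 0 to 1 for B and 1 to 2 for D. The iNKT share for B ran from 6.602 to 11.6 and passed each time. With 4 against 4 libraries, passing depends on how many of the 5 comparisons reach the smallest exact p. For the iNKT share C and D reached it too, since every Treg library held 0. That it passed does not rank it above calls that ended.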

Other observations

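Apart from the edgeR fit of clonotypes, the tests in this part were chosen after the data had been seen, as were the clonotypes named. The TRAV11-TRAJ18 rearrangement also carried CDR3 sequences close to the iNKT receptor, all in Tcell libraries: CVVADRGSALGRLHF with 14 counts in 4 libraries and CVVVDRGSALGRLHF with 11 counts in 7 libraries, against 359 counts of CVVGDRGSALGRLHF in 10. None of them occurred in the 15 Treg libraries. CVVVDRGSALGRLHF took 0.448% ± 0.428 of resident and 0.0675% ± 0.0509 of circulating Tcell counts (n = 5 each), with a log2 fold change of 2.54 (SE 1.28, edgeR adjusted p = 0.375). The receptor of mucosal-associated invariant T cells had 1 count in all, in resident Tcell 2.

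Same-number resident and circulating Tcell libraries had 211 shared nucleotide clonotypes in total, against 71 for resident and circulating Treg, 55 for circulating Treg and circulating Tcell, 20 for siMLN and coMLN resident Treg and 8 for resident Treg and resident Tcell. Shared clonotypes were 22.9% ± 5.47 of resident Tcell and 2.87% ± 1.77 of resident Treg clonotypes (n = 5 each). These counts are at full depth, which ran from 702 counts in coMLN Treg to 9599 in circulating Tcell, so they do not rank the pairs. Drawn to 127 counts, the means were 5.83 for resident and circulating Tcell, 1.43 for resident and circulating Treg, 0.374 for circulating Treg and circulating Tcell and 0.226 for resident Treg and resident Tcell. The percents were then 5.67% ± 0.716 and 1.17% ± 0.608. The values for resident and circulating Tcell, here and at full depth, include iNKT sequences, which no Treg library held. They were not computed without these. Drawn to 42 counts, siMLN and coMLN resident Treg shared 0.206 and resident and circulating Treg 0.176 (n = 5 each).

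Of 100 splits of the libraries of a comparison into groups of the same sizes, the real one included, some gave as many calls as the real groups. Chance was judged unlikely where fewer than 5 in 100 did, also where another split reached or passed the real count. These fractions were not adjusted over the counts tested, so chance is not excluded for any of them. This concerns the number of calls and not a single segment: the exact permutation test of the TRAV11 share had an unadjusted p of 0.00794, the smallest possible, for resident against circulating Tcell and for resident Treg against resident Tcell. For the number of V segments, chance was judged unlikely for circulating Treg against circulating Tcell (2 splits gave as many, 3 calls, highest other split 4). With 1 library number left out the count was 1 (without 1, 4 or 5) or 2 (without 2 or 3). It was not judged unlikely for resident against circulating Tcell (5 splits, 2 calls, highest other 2), resident Treg against resident Tcell (9 splits, 1 call, highest other 2) or the interaction (8 splits, 1 call, highest other 1). These counts were 1 whichever number was left out, 2 without number 3 or 4, and 0 without number 1, in that order. For J segments it was judged unlikely for resident against circulating Tcell (1 split, 3 calls, highest other 2) and resident Treg against resident Tcell (4 splits, 2 calls, highest other 2). The first count was 0 without number 2 and the second 1 without number 1 or 2. It was not judged unlikely for circulating Treg against circulating Tcell (9 splits, 1 call, highest other 1, and 0 calls without number 2). For V subgroups it was judged unlikely for resident against circulating Tcell (2 splits, 3 calls, highest other 3), resident Treg against resident Tcell (3 splits, 3 calls, highest other 3) and the interaction (3 splits, 1 call, highest other 2). These counts were 2 without number 2 or 3, 2 without number 5, and 0 without number 1 or 2 without number 3, in that order. It was not judged unlikely for circulating Treg against circulating Tcell (10 splits, 1 call, highest other 1). For clonotypes it was judged unlikely for circulating Treg against circulating Tcell (4 splits, 2 calls, highest other 2), though the count was 1 without number 2, 3 or 5. Where edgeR called 0, all 100 splits gave as many by construction: resident against circulating Treg (highest other split 0 for V segments and V subgroups, 1 for J segments and clonotypes), coMLN against siMLN (1 for V, J and V subgroups), the J interaction (2) and clonotypes in resident against circulating Tcell (3, with 1 call without number 2). For V subgroups, which DESeq2 was not run on, the counts at an unadjusted p under 0.05 in edgeR were 0 for resident against circulating Treg and 1 for coMLN against siMLN. For the other counts of 0 the report gives the unadjusted counts, and the DESeq2 counts except for the interaction.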
